A study of Homo sapiens with 18 samples.

How the data were processed

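RNA-seq was carried out on HCC95 cells, a human lung squamous cell carcinoma line. Per the labels' protocols, 200000 cells were plated per well, siRNAs were transfected at 30 nM the next day, and TNF was given at 10 ng/ml for 4 hours. Total RNA was extracted and first strand cDNA was primed with dT oligonucleotides, per the labels' protocols. There were 18 libraries in 6 groups of 3: control, ALAL1 or SART3 siRNA, each with or without TNF. The labels call the replicates separate samples but do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

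The deposited table held 1 signal value per gene and library, namely gene read counts that the authors divided by 1 size factor per library and rounded to 2 decimals. The submitters' processing notes name bcl2fastq, FastQC, Trimmomatic, STAR, featureCounts and DESeq2 and the hg19 build, without roles or versions. The annotation release, the strand setting and any filter are not given in the sources used here, so reads shared between overlapping, antisense or near-identical genes could not be separated. All 18 columns were matched to samples by name. In every library, 100% of the nonzero values were whole multiples of 1 step within 0.006 normalized counts, a tolerance set after the residuals were seen. The recovered reads per library ran from 5806614 to 8909718. Of the 55765 rows, 23915 were 0 in every library. The reference tables matched 30717 row names to a current symbol and 2096 to 1 older symbol, and 22952 matched neither. The mitochondrially encoded genes were listed at 0 in every library.

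The values were analysed as log2(normalized count + 1), and fold changes are on that scale, which understates the change of low genes. Genes with a normalized count of at least 10 in at least 3 libraries were kept, which left 15811. One limma model (limma 3.58.1, R 4.3.3, lmFit, contrasts.fit and eBayes with trend) with a mean per group was fitted over all 18 libraries, so that the groups shared 1 estimate of the spread. There were 9 contrasts: TNF against no TNF under each siRNA, each knockdown against control with and without TNF, and the 2 knockdown-by-TNF interactions. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 within a contrast. Means are given with their SD over the 3 libraries of a group.

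Gene lists were fixed before the data were examined, as were the design, the naming rule and the alternatives not described as added. They covered NF-kB target genes, chemokines and cytokines, interferon-stimulated genes, antigen presentation, immune checkpoint ligands, NF-kB and TNF signalling components, U4/U6 snRNP recycling and tri-snRNP, G1/S and G2/M cell cycle genes, replication-dependent histone genes, p53 target genes, apoptosis regulators, unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol biosynthesis, oxidative phosphorylation, cytosolic ribosomal proteins, squamous epithelial genes, epithelial-mesenchymal transition and matrix genes, fibroblast, leukocyte and endothelial markers, and mitochondrially encoded genes. Each list was tested with camera (limma, preset inter-gene correlation 0.01, two-sided) with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. Gene counts within a list are given over all genes tested and adjusted over the list alone. Lists of TNF-induced genes were genes called higher with a log2 fold change of at least 1 in the other knockdown, so that the list and the comparison shared no library. Their p-values were adjusted over the 6 tests of these lists, a choice made after the values were seen.

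For each of the first 5 contrasts, the named genes were the 10 higher and 10 lower genes with the largest absolute fold change among those called, with no overlap between the replicates of the groups and a mean of at least 50 in the higher group. For the other TNF effects and the interactions the number was 5 per direction, without the overlap condition for the interactions. Up to 4 members with the smallest adjusted p were named per described list. SART3, USP4 and RELA were named in the knockdown contrasts whatever their values. Genes without a gene symbol were passed over. One gene that the rule names is not reported here. An exploratory fit was looked at before the condition on symbols was coded. The ALAL1 transcript was not analysed here, since neither the table nor the reference tables used here pair a row with that name.

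The alternatives were other pseudocounts (0.5 and 5), other filters on low values, other scalings, robust or weighted fits, a fit of the compared groups alone, a replicate block, an added fold change minimum, each replicate left out, and count models on the recovered reads (edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0). Fits without control siRNA + TNF replicate 3 were added for all contrasts after the data were seen. Overlaps of the knockdowns, which share control libraries, were set beside 50 simulations of unchanged groups and beside the overlap of independent lists.

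The model was tested on simulated counts drawn from the real means and library sizes, with 15811 genes of which 200 were changed. For the ALAL1 knockdown without TNF it recovered 59% of the genes changed by a log2 of 1 and 87% of those changed by 2, with 3.31% false among the calls. For the ALAL1 interaction it recovered 50% and 76%, with 5.26% false. Presence of 7-base sequences in annotated 3′ UTRs (GENCODE v29, 12222 of 12286 protein-coding genes tested) was scanned against the fold changes with UTR length and GC content as covariates. In that scan 20 of 20 7-mers planted with a log2 effect of -0.4 in shuffled fold changes ranked first. Smaller effects were not planted. The scan was added after the largest falls had been seen. No coordinates are given, because the reference used here is of another build than the deposited table.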

Results

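Gene expression was measured by RNA-seq in HCC95 cells, a human lung squamous cell carcinoma line, to follow the transcriptome after knockdown of the long noncoding RNA ALAL1 or of SART3, with and without the cytokine TNF. Control, ALAL1 and SART3 siRNA were each combined with no TNF or TNF, giving 6 groups of 3 libraries. The recovered reads per library ranged from 5806614 to 8909718, and 15811 genes were tested. Levels below are normalized read counts, mean ± SD with n = 3, and fold changes are limma log2 values.

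SART3, a factor of U4/U6 snRNP recycling, was at 629.7 ± 33.7 with control siRNA and 160.5 ± 10.6 with SART3 siRNA, a log2 change of -1.97 (limma, Benjamini-Hochberg adjusted p = 6.1e-09). With TNF the levels were 576 ± 4.34 and 155 ± 22.7, a log2 change of -1.90 (limma, Benjamini-Hochberg adjusted p = 2.27e-08). Under ALAL1 siRNA, SART3 was at 604 ± 94.9 without TNF and 577 ± 31.7 with TNF, and neither value passed the test against its control. The ALAL1 transcript was not analysed here, so the ALAL1 knockdown was not checked on its target.

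**Figure D1:**
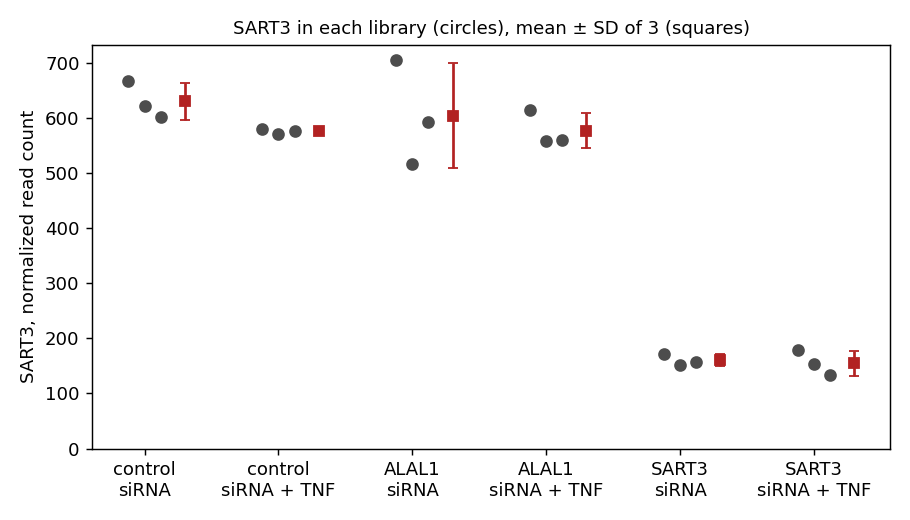
SART3 normalized read count (y axis, linear from 0) in each of the 18 libraries (circles) by group (x axis), with the mean and SD of 3 libraries (squares). The SART3 siRNA groups averaged 160.5 and 155, against 629.7 and 576 in their control groups.

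TNF in control siRNA cells raised the classical inflammatory genes. TNFAIP2 rose from 249.9 ± 14.6 to 1385 ± 168 (log2 2.46) and TNFAIP3, which encodes the A20 feedback inhibitor of NF-kB, rose by a log2 of 1.88. CSF2, which encodes GM-CSF, rose by 2.98, the acute phase gene PTX3 by 2.96, FGF18 by 2.48, IL1B by 2.39, lymphotoxin beta (LTB) by 2.22, the neutrophil chemokine CXCL3 by 2.22, TRAF1 by 2.07 and EFNA1 by 2.03. STX11 went from 28.2 ± 5.24 to 116.6 ± 29.2. Of the 40 NF-kB target genes measured, 33 rose, 0 fell and 7 did not pass, and 35 rose when adjusted over the list alone (median log2 1.18, camera, Benjamini-Hochberg adjusted p = 1.03e-68). Of 28 chemokines and cytokines, 18 rose, 0 fell and 10 did not pass, with 20 higher and 1 lower adjusted over the list alone (median 1.10, camera, Benjamini-Hochberg adjusted p = 6.64e-30). CCL2, a monocyte chemokine, went from 3812 ± 507 to 10340 ± 1070, and CSF1 and EBI3 rose by 1.67 and 1.36. NF-kB and TNF signalling components had 8 of 29 higher and 0 lower, 10 and 1 adjusted over the list alone, among them the NF-kB subunits NFKB1 (1.37) and NFKB2 (1.51) and the inhibitor NFKBIA (1.66) (camera, Benjamini-Hochberg adjusted p = 6.35e-06).

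Smaller rises were found in antigen presentation genes, with 5 of 20 higher and 10 adjusted over the list alone (median 0.27), including HLA-F (0.67), TAP1 (0.56) and TAPBP (0.70). Interferon-stimulated genes had 4 of 32 higher and 6 adjusted over the list alone (median 0.18), including the RNA sensor gene DDX58 (0.49) and IFIT3 (0.44). Apoptosis regulators had 8 of 30 higher and 1 lower, 12 and 2 adjusted over the list alone, led by the inhibitor of apoptosis BIRC3 (1.64). Unfolded protein and integrated stress response genes had 4 of 28 higher and 7 adjusted over the list alone, including CEBPB (0.80) and XBP1 (0.47). The camera Benjamini-Hochberg adjusted p was 1.16e-07, 0.00142, 1.4e-07 and 2.23e-06 for these 4 lists, and all 4 held with an estimated correlation. The p53 target genes had 5 of 28 higher, 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.019, and adjusted p = 0.0762 with an estimated correlation). The genes with the largest falls were ANKRD1 (-1.84), the orphan receptor NR4A1 (-1.30), ARID5B (-1.27), CTGF (-1.20), PLEKHH2 (-1.18), IER5L (-1.13), the Hedgehog receptor PTCH1 (-1.04), the noncoding RNA MALAT1 (-1.03) and HMX1 (-0.99). The pseudogene HSP90AB3P also fell (-1.35) and is uncertain, because it can share reads with its parent gene.

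In all, 453 genes passed limma at a Benjamini-Hochberg adjusted p under 0.05, 310 higher and 143 lower with TNF. Rescaling to the same total gave 228 higher and 235 lower, with a median shift of all genes of -0.07. The count was 269 without control siRNA replicate 1 and 294 without control siRNA replicate 2, and 379 without control siRNA + TNF replicate 3, the library farthest from its group (mean absolute deviation 0.259 on the log2 scale, against at most 0.212 in the others). Without control siRNA replicate 1 the limma Benjamini-Hochberg adjusted p was 0.0568 for MALAT1 and 0.0923 for HMX1.

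**Figure D2:**
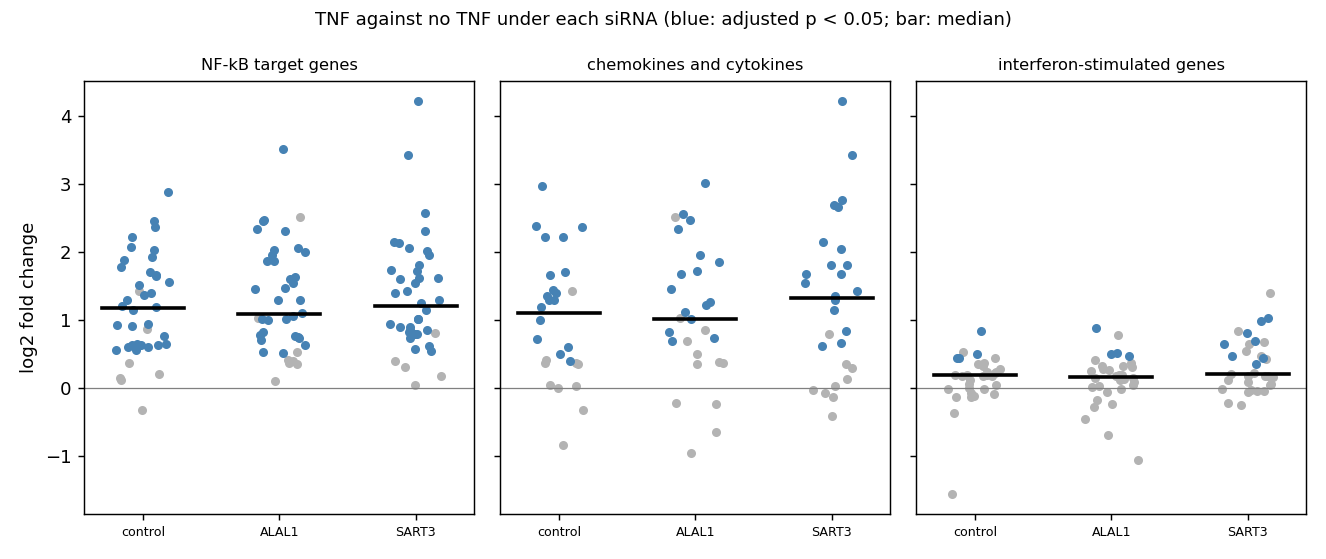
Log2 fold change with TNF (y axis) of each measured member of 3 gene lists under control, ALAL1 or SART3 siRNA (x axis); blue points passed limma at an adjusted p under 0.05, grey points did not, and bars are medians. The NF-kB target medians were 1.18, 1.08 and 1.20, and those of the interferon-stimulated genes 0.18, 0.16 and 0.21.

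Under ALAL1 siRNA, TNF also raised the NF-kB target genes and the chemokines and cytokines as lists. Of 40 NF-kB target genes 32 rose, 0 fell and 8 did not pass, 37 higher adjusted over the list alone (median 1.08), and of 28 chemokines and cytokines 16 rose and 0 fell, 22 higher and 1 lower adjusted over the list alone (median 1.02). PTX3 rose by 3.08, CSF2 by 3.02, the sphingosine phosphatase SGPP2 by 2.79, LTB by 2.57 and TNFAIP2 by 2.46. The largest falls were in ANKRD1 (-1.30), MIR503HG (-1.14), the matrix gene CYR61 (-1.06), IER5L (-1.01) and ID2 (-0.95). The camera Benjamini-Hochberg adjusted p was 6.68e-81 and 3.38e-33 for these lists. Antigen presentation genes (3 of 20 higher, 7 adjusted over the list alone) and interferon-stimulated genes (4 of 32 higher, 4 and 1 lower adjusted over the list alone) passed as well, with camera Benjamini-Hochberg adjusted p = 1.87e-06 and 0.00299. So did the p53 target genes (4 of 28 higher, 4 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.00166). Squamous epithelial genes (2 of 31 higher, among them LAMB3 at 0.78) and epithelial-mesenchymal transition and matrix genes (2 of 26 higher and 2 lower) passed camera with Benjamini-Hochberg adjusted p = 0.0279 and 0.0238, but with an estimated correlation the adjusted p was 0.173 and 0.0852. In total 412 genes were called by limma, 333 higher and 79 lower, and 234 higher and 102 lower after rescaling to the same total. The count was 269 without ALAL1 siRNA replicate 2, 256 without ALAL1 siRNA replicate 3 and 264 without ALAL1 siRNA + TNF replicate 2, and without ALAL1 siRNA + TNF replicate 3 the limma Benjamini-Hochberg adjusted p of IER5L was 0.0885.

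Under SART3 siRNA, TNF raised 35 of 40 NF-kB target genes, 38 adjusted over the list alone (median 1.20), and 19 of 28 chemokines and cytokines, 21 adjusted over the list alone (median 1.32), with 0 lower in either list (camera, Benjamini-Hochberg adjusted p = 3.71e-61 and 9.87e-27). IL8, a neutrophil chemokine, rose by 4.23, PTX3 by 3.69, the chemokine CCL20 by 3.44, the BCL2 family gene BCL2A1 by 3.06 and IL1A by 2.77. The libraries spread widely for 4 of these 5 genes: IL8 was at 214.8, 3064 and 857 in SART3 siRNA + TNF replicates 1, 2 and 3, whereas PTX3 was at 145, 141 and 144. Without replicate 2, the limma Benjamini-Hochberg adjusted p was 0.0631 for IL8 (log2 3.29) and 0.0746 for IL1A (log2 2.22), and the rises of CCL20 and BCL2A1 were 2.38 and 2.19. Without replicate 1 IL8 rose by 5.20, and without replicate 3 CCL20 rose by 4.18. Without SART3 siRNA replicate 1 the rise of IL8 was 3.44, and without SART3 siRNA replicate 2 that of PTX3 was 3.09. BMF, a pro-apoptotic gene, fell by a log2 change of -1.33, NR4A1 by -1.31, HOXC13 by -1.05, CTGF by -1.04 and the growth factor signalling inhibitor SPRY1 by -1.02. Hypoxia and glycolysis genes were lower as a list (0 of 32 higher, 2 lower, 2 adjusted over the list alone, median -0.11, camera, Benjamini-Hochberg adjusted p = 0.00321), with falls in the glucose transporter genes SLC2A3 (-0.73) and SLC2A1 (-0.44). Interferon-stimulated genes had 8 of 32 higher and 0 lower, 10 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000114). Antigen presentation passed camera (1 of 20 higher, 4 adjusted over the list alone, Benjamini-Hochberg adjusted p = 0.0118) but had an adjusted p = 0.156 with an estimated correlation. In total 651 genes were called by limma, 484 higher and 167 lower, and 354 and 233 after rescaling to the same total, or 378 and 274 by upper quartile. The count was 330 without SART3 siRNA replicate 3, and 1199, 349 and 389 without SART3 siRNA + TNF replicate 1, 2 or 3. Without SART3 siRNA replicate 3 the limma Benjamini-Hochberg adjusted p of BMF was 0.0582.

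ALAL1 siRNA without TNF lowered 1173 genes and raised 806, although with upper quartile scaling 1001 were lower and 1094 higher. The largest falls were in MFAP3 (-2.04), the thrombin receptor family gene F2RL2, from 607 ± 13.7 to 161 ± 27.6 (-1.92), the small GTPase gene RHOD (-1.82), the calcium pump genes ATP2B1 (-1.81) and ATP2B4 (-1.64), the importin IPO4 (-1.79), RNF157 (-1.77), the topoisomerase TOP2A (-1.76), spermine synthase (SMS, -1.75) and PREX1 (-1.73). Of these 10 genes, 9 carried the 7-base sequence GACATCA, which was chosen on this comparison, in the annotated 3′ UTR, against 1020 of 12222 genes searched. The largest rises were mostly in pseudogenes, which can share reads with their parent genes and are uncertain: AKR1B10P1 (2.07), RPS18P12 (1.84), RANP1 (1.83), SNRPD2P1 (1.82), KRT8P33 (1.79), FAM207BP (1.67), RPS2P5 (1.49) and TCEB1P2 (1.44). The protein-coding genes among the largest rises were ARF5 (1.76) and LYRM9 (1.54). Of these 10 rises, 8 lost the call when 1 library of either group was left out, with limma Benjamini-Hochberg adjusted p up to 0.156 (TCEB1P2, without control siRNA replicate 3); AKR1B10P1 and LYRM9 kept it.

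The p53 target genes rose under ALAL1 siRNA, with 13 of 28 higher, 1 lower and 14 not past the test, 14 and 1 adjusted over the list alone (median 0.40, camera, Benjamini-Hochberg adjusted p = 1.72e-06). CDKN1A, the p21 cell cycle inhibitor, went from 2590 ± 123 to 4936 ± 108, the DNA repair gene XPC rose by 0.78 and the stress cytokine GDF15 by 0.64, whereas cyclin G1 (CCNG1) fell (-1.12). CCNG1 was among the 5 members of the list with GACATCA in the 3′ UTR, whose median was -0.083. The 23 members without it had a median of 0.451, with 12 higher and 0 lower. Interferon-stimulated genes had 7 of 32 higher and 0 lower, 10 adjusted over the list alone (median 0.27, camera, Benjamini-Hochberg adjusted p = 0.000577), including IFIT3 (0.78), IFIT1 (0.66) and the RNA sensor IFIH1 (0.65). G2/M cell cycle genes had 2 of 53 higher and 12 lower, the same counts adjusted over the list alone, among them the proliferation marker MKI67 (-1.18), LBR (-1.52), NUSAP1 (-0.92) and ECT2 (-1.10). That list passed camera (Benjamini-Hochberg adjusted p = 0.0024) but had an adjusted p = 0.341 with an estimated correlation. Its 3 members with GACATCA in the 3′ UTR had a median of -1.178. The 49 searched members without it there had a median of -0.119, with 2 higher and 9 lower. NF-kB target genes did not pass as a list (2 of 40 higher, 7 lower, 2 and 8 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.311). Its 36 searched members without GACATCA in the 3′ UTR had a median of -0.08, with 1 higher and 7 lower (camera, Benjamini-Hochberg adjusted p = 0.0756). Its called members included TNFAIP2 (-1.04) and CXCL1 (-0.52). The chemokines and cytokines did not pass either (0 of 28 higher, 5 lower, 1 and 7 adjusted over the list alone, camera, Benjamini-Hochberg adjusted p = 0.0732, median -0.17), and none carried GACATCA in the 3′ UTR. IL11 (-1.54) and CCL2 (-0.83) were among the 5 lower. The NF-kB subunit RELA (-0.06) and the deubiquitinase USP4 (0.22) did not pass the test.

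In total 1979 genes were called by limma. The count was 1219 without control siRNA replicate 2, 1240 without control siRNA replicate 3 and 1100 without ALAL1 siRNA replicate 2, and 2428 with control siRNA + TNF replicate 3 left out of the fit.

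With TNF present, ALAL1 siRNA lowered RHOD (-1.94), the cytokine gene TGFB1 (-1.79), the NKG2D ligand gene ULBP2 (-1.75), the phosphatase CTDSP1 (-1.73), RNF157 (-1.72), F2RL2 (-1.72), HEBP2 (-1.71), IPO4 (-1.69), SMS (-1.66) and FAM58A (-1.61). Of these 10 genes, 9 carried GACATCA in the annotated 3′ UTR. The largest rises were in the interferon lambda gene IFNL2 (1.70, from 17.6 ± 2.64 to 58.9 ± 3.76), the p53-induced gene SESN1 (1.49), SLC2A3 (1.40), TRIM31 (1.40), MAP2 (1.27), PLEKHH2 (1.20), the transcription factor RUNX2 (1.14), DNAH5 (1.10), LYRM9 (1.09) and SCML2 (1.08). IFNL2 has near-identical family members, so its value is uncertain. TRIM31 had a limma Benjamini-Hochberg adjusted p of 0.0689 without control siRNA + TNF replicate 2. The p53 target genes had 14 of 28 higher and 1 lower, 16 and 1 adjusted over the list alone (median 0.48, camera, Benjamini-Hochberg adjusted p = 7.65e-08), with XPC at 0.80 and BTG2 at 0.76. The 5 members with GACATCA in the 3′ UTR had a median of 0.101, and the 23 without it 0.55, with 12 higher and 0 lower. Interferon-stimulated genes had 6 of 32 higher and 1 lower, 7 and 1 adjusted over the list alone (median 0.25, camera, Benjamini-Hochberg adjusted p = 0.000836), with IFIT1 at 0.79 and IFIH1 at 0.74. G2/M genes had 1 of 53 higher and 12 lower, 2 and 14 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0132, and adjusted p = 0.433 with an estimated correlation). The 3 members with GACATCA in the 3′ UTR had a median of -1.104, and the 49 searched members without it there -0.056, with 1 higher and 9 lower. NF-kB target genes had 2 of 40 higher and 4 lower, 5 and 7 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.811), and the 36 members without GACATCA in the 3′ UTR had an adjusted p = 0.649. Chemokines and cytokines had 1 of 28 higher and 5 lower, 2 and 7 adjusted over the list alone (median -0.28, camera, Benjamini-Hochberg adjusted p = 0.0867). The list passed without control siRNA + TNF replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.0359). RELA (-0.18) and USP4 (0.22) did not pass the test. In total 1668 genes were called by limma, 635 higher and 1033 lower, and 885 and 890 with upper quartile scaling. The count was 993 without control siRNA + TNF replicate 3, 1062 without ALAL1 siRNA + TNF replicate 2 and 937 without ALAL1 siRNA + TNF replicate 3.

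SART3 siRNA without TNF lowered more genes than it raised. Apart from SART3 itself, the largest falls were in the kinase gene NEK7, from 334 ± 14.6 to 64.2 ± 7.81 (-2.37), the Golgi gene GOPC (-2.23), HSD17B11 (-2.14), SPA17 (-1.99), OSTC (-1.85), the ubiquitin ligase UBE4A (-1.80), AMMECR1 (-1.72), C9orf40 (-1.68) and APIP (-1.67). Of the 10 genes with SART3 included, 8 carried the 7-base sequence AAATGAA, also chosen on this comparison, in the annotated 3′ UTR, against 3353 of 12222 genes searched. The largest rises were in ACTA2 (1.34), the pro-apoptotic p53 target genes BBC3 (1.05) and BAX (0.92), SESN1 (1.02), RERG (0.95), FDXR (0.92), endothelin 2 (EDN2, 0.90), LYRM9 (0.85), the calcium channel gene ORAI3 (0.82) and the pseudogene HLA-Z (0.82), which can share reads with other HLA genes. The calls of RERG, LYRM9, ORAI3, HSD17B11 and SPA17 were lost when 1 library was left out. HSD17B11 was at 117.8 ± 109 in the control libraries, and without control siRNA replicate 2 its log2 change was -1.42 (limma, Benjamini-Hochberg adjusted p = 0.211). The p53 target genes had 17 of 28 higher, 0 lower and 11 not past the test, 20 adjusted over the list alone (median 0.50, camera, Benjamini-Hochberg adjusted p = 1.3e-18), including CDKN1A (0.59) and the repair gene DDB2 (0.65).

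NF-kB target genes were lower as a list, with 0 of 40 higher and 7 lower, 10 lower adjusted over the list alone (median -0.21, camera, Benjamini-Hochberg adjusted p = 6.69e-05), including CXCL3 (-0.78), KLF6 (-0.54), CXCL1 (-0.54) and PLAU (-0.36). The 14 members with AAATGAA in the 3′ UTR had a median of -0.33 and the 25 searched members without it -0.18. Chemokines and cytokines had 0 of 28 higher and 6 lower, 9 adjusted over the list alone (median -0.29, camera, Benjamini-Hochberg adjusted p = 0.000205), with CCL2 from 3812 ± 507 to 2015 ± 47.2 and CXCL5 at -1.17. Its 7 members with AAATGAA had a median of -0.78 and the 21 without it -0.20. Cholesterol biosynthesis genes had 5 of 23 higher and 2 lower, 8 and 2 adjusted over the list alone (median 0.21, camera, Benjamini-Hochberg adjusted p = 0.00101). DHCR7 (0.57) and IDI1 (0.36) rose, whereas SQLE (-0.44) and TM7SF2 (-0.51), enzymes of the same pathway, fell. SQLE and TM7SF2 were among the 9 members with AAATGAA in the 3′ UTR, whose median was 0.155. The 14 members without it had a median of 0.295, with 5 higher and 0 lower. Squamous epithelial genes had 0 of 31 higher and 5 lower, 7 adjusted over the list alone (median -0.27, camera, Benjamini-Hochberg adjusted p = 0.000841, and adjusted p = 0.0668 with an estimated correlation), among them the integrin ITGA6 (-1.26), keratin KRT6A (-0.48) and the squamous transcription factor TP63 (-0.55). RELA (0.22) and USP4 (0.003) did not pass the test. In total 994 genes were called by limma, 287 higher and 707 lower. The count was 497 without control siRNA replicate 1, 431 without control siRNA replicate 2, 612 without SART3 siRNA replicate 2 and 516 without SART3 siRNA replicate 3.

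With TNF present, SART3 siRNA lowered NEK7 (-1.92), GOPC (-1.69), C9orf40 (-1.58), RBPMS2 (-1.54), GDF11 (-1.53), APIP (-1.53), ITGA6 (-1.28), the uridine kinase UCK2 (-1.25) and the centromere gene CENPP (-1.22) besides SART3. Of these 10 genes, 7 carried AAATGAA in the annotated 3′ UTR. SESN1 (1.40), ACTA2 (1.12), CYFIP2 (1.03), PEX2 (1.02), CLGN (1.02), SOX4 (0.98), EDA2R (0.97), ZMAT3 (0.89), the death receptor gene FAS (0.87) and SCARNA13 (0.87) had the largest rises. Of these, PEX2, CLGN, SOX4, EDA2R and SCARNA13 lost the call when 1 library was left out, with limma Benjamini-Hochberg adjusted p up to 0.232 (CLGN, without SART3 siRNA + TNF replicate 2). The p53 target genes had 9 of 28 higher and 0 lower, 19 adjusted over the list alone (median 0.47, camera, Benjamini-Hochberg adjusted p = 7.13e-18). NF-kB target genes had 0 of 40 higher and 6 lower, 7 adjusted over the list alone (median -0.15), and chemokines and cytokines had 0 of 28 higher and 6 lower, 1 higher and 10 lower adjusted over the list alone (median -0.18); both lists had a camera Benjamini-Hochberg adjusted p = 0.000425. CXCL3 went from 986 ± 95.4 to 547 ± 25.3, CXCL5 fell (-1.07), and so did CXCL2 (-0.66) and TNFAIP2 (-0.51). Squamous epithelial genes had 0 of 31 higher and 6 lower, 10 adjusted over the list alone (median -0.34, camera, Benjamini-Hochberg adjusted p = 7.61e-08), with KRT6A at -0.50 and KRT15 at -0.80. Hypoxia and glycolysis genes had 0 of 32 higher and 2 lower, 3 adjusted over the list alone (median -0.14, camera, Benjamini-Hochberg adjusted p = 0.00069), with NDRG1 at -0.97 and SLC2A3 at -0.43. Cholesterol biosynthesis genes had 5 of 23 higher and 1 lower, 7 and 1 adjusted over the list alone (median 0.20, camera, Benjamini-Hochberg adjusted p = 0.000333), with IDI1 at 0.45 and FDFT1 at 0.43 but TM7SF2 at -0.61. TM7SF2 was among the 9 members with AAATGAA in the 3′ UTR, whose median was 0.195. The 14 members without it had a median of 0.192, with 4 higher and 0 lower. Cytosolic ribosomal proteins passed camera with 0 of 76 members called (Benjamini-Hochberg adjusted p = 0.0157, and adjusted p = 0.611 with an estimated correlation), and the list did not pass without control siRNA + TNF replicate 3 (adjusted p = 0.483). RELA (0.001) and USP4 (-0.16) did not pass the test. In total 348 genes were called by limma, 70 higher and 278 lower. The count was 230 without SART3 siRNA + TNF replicate 2 (25 higher) and 516 without replicate 1 (226 higher), and 41, 45 and 44 genes were higher without SART3 siRNA + TNF replicate 3 or control siRNA + TNF replicate 1 or 3.

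**Figure D3:**
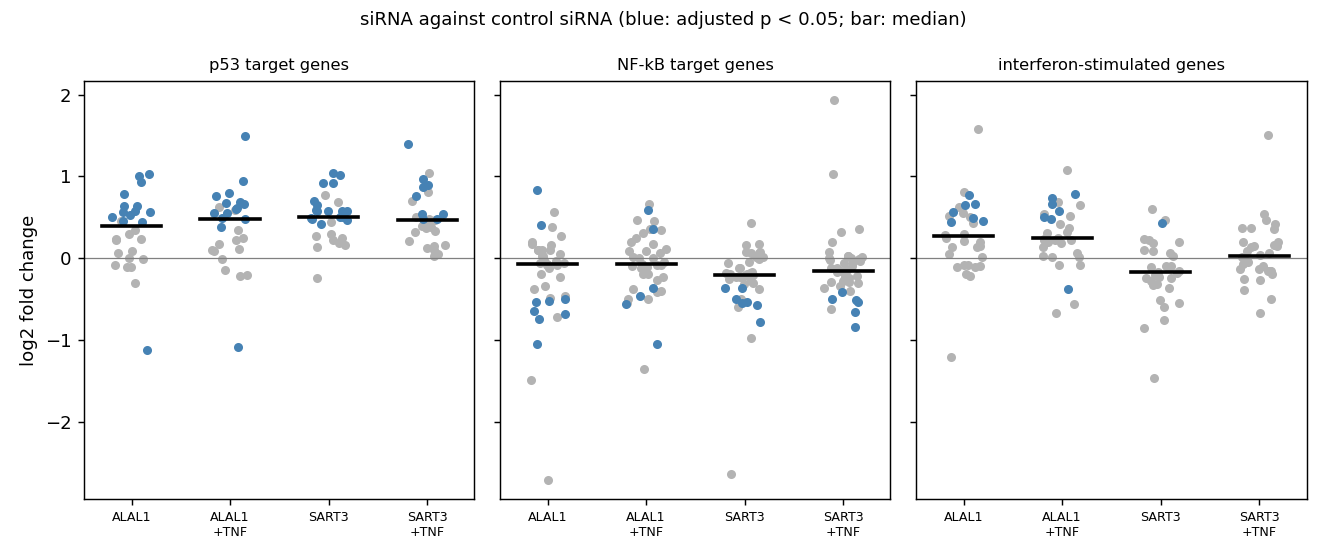
Log2 fold change of each siRNA against control siRNA (y axis) of each measured member of 3 gene lists, without and with TNF (x axis); blue points passed limma at an adjusted p under 0.05, grey points did not, and bars are medians. The p53 target medians were 0.40 and 0.48 under ALAL1 siRNA and 0.50 and 0.47 under SART3 siRNA.

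The genes induced by TNF were next compared between knockdown and control cells, with camera p-values adjusted over the 6 tests made on the lists. The 138 genes induced at least by a log2 of 1 in the SART3 siRNA libraries had a median log2 change of -0.04 under ALAL1 siRNA with TNF, with 3 genes higher and 13 lower (camera, Benjamini-Hochberg adjusted p = 0.656). Their median was -0.10 under ALAL1 siRNA without TNF and 0.12 for the ALAL1 by TNF interaction. These passed (camera, Benjamini-Hochberg adjusted p = 0.0457 and 0.0318), but the adjusted p = 0.243 for both with an estimated correlation. The 119 genes induced in the ALAL1 siRNA libraries had a median of -0.19 under SART3 siRNA with TNF, with 0 higher and 8 lower (camera, Benjamini-Hochberg adjusted p = 6.36e-05, and adjusted p = 0.0236 with an estimated correlation). The same 119 genes had a median of -0.14 under SART3 siRNA without TNF, with 1 higher and 16 lower (camera, Benjamini-Hochberg adjusted p = 0.000372). Their SART3 by TNF interaction had a median of -0.03 (camera, Benjamini-Hochberg adjusted p = 0.992). The 119 genes were not split by AAATGAA in the 3′ UTR, so a part of that sequence in their lower values stays open. It was in 32.9% of the searched genes called higher by TNF under ALAL1 siRNA.

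The interaction terms asked whether the response to TNF differed under each knockdown. No gene passed limma for either interaction at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 550 genes for ALAL1 and 1926 for SART3. The edgeR quasi-likelihood test on the recovered reads called 0 and 0, and DESeq2 called 0 and 141 (126 with a positive and 15 with a negative interaction). For SART3 the count was 239 without SART3 siRNA + TNF replicate 1 (228 positive and 11 negative), 2 without control siRNA + TNF replicate 2 and 6 without SART3 siRNA replicate 1. NF-kB target genes had a median interaction of 0.11 for ALAL1 and -0.05 for SART3 (camera, Benjamini-Hochberg adjusted p = 0.378 and 0.683). Hypoxia and glycolysis genes passed for SART3 with a median of -0.20 (camera, Benjamini-Hochberg adjusted p = 0.0138, and adjusted p = 0.0443 with an estimated correlation) and 0 members called.

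Both knockdowns were compared with the same control libraries, so their overlap is given beside chance values. Without TNF, 62 genes were higher under both siRNAs, including the p53 target genes CDKN1A, BBC3 and SESN1, 120 were lower under both and 53 were called in opposite directions. Independent lists of these sizes would share 14.6 and 52.5 genes, and simulated unchanged groups shared 0. The first value leaves out the shared controls, and unchanged groups hold few calls to share. Over all genes, 60% of fold changes had the same sign in both comparisons, below the 66.7% of unchanged groups, and with TNF 62% against 66.7%. The covariance of the fold changes across genes was 0.057 against a simulated 0.0334 (correlation 0.34 against 0.50). With TNF, 20 genes were higher and 45 lower under both and 27 went in opposite directions, against 2.81 and 18.2 for independent lists. The covariance was 0.0533 against 0.0331 (correlation 0.36 against 0.50). With 3 controls no split kept at least a pair of libraries on each side. Across TNF states the knockdowns share no control library. ALAL1 siRNA without TNF and SART3 siRNA with TNF had 14 genes higher, 38 lower and 33 opposite, against 3.57, 20.6 and 19.4 for independent lists (covariance 0.0134, 53.8% of the same sign). ALAL1 siRNA with TNF and SART3 siRNA without TNF had 35, 62 and 72, against 11.5, 46.2 and 47.1 (covariance 0.00631, 49.3% of the same sign). Part of the excess within a TNF state may come from the shared controls. The count in the same direction fell from 182 to 80, 69 and 120 without control siRNA replicate 1, 2 or 3, to 101 without ALAL1 siRNA replicate 2, and to 103 and 113 without SART3 siRNA replicate 2 or 3. With TNF it fell from 65 to 29 without control siRNA + TNF replicate 3, to 42 without ALAL1 siRNA + TNF replicate 2, and to 40 and 35 without SART3 siRNA + TNF replicate 2 or 3.

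Of the 45 list results that passed camera, 37 also passed with an estimated correlation. Several lists did not pass camera in any of the 9 contrasts with all libraries. They were immune checkpoint ligands, U4/U6 snRNP recycling and tri-snRNP, G1/S cell cycle genes, replication-dependent histone genes, oxidative phosphorylation, and fibroblast and leukocyte markers. Without control siRNA + TNF replicate 3, the histone genes passed under SART3 siRNA with TNF (0 higher, 2 lower, median -0.24, camera, Benjamini-Hochberg adjusted p = 0.00243), as did the epithelial-mesenchymal transition and matrix genes (adjusted p = 0.0307). Both tests used the preset correlation. With all libraries, the 5 histone genes with AAATGAA in the 3′ UTR had a median of -0.461 in that contrast. The 8 searched without it had a median of 0.024, with 0 higher and 0 lower. The cytosolic ribosomal proteins passed without control siRNA + TNF replicate 3 for TNF in control cells, ALAL1 siRNA without TNF and the ALAL1 by TNF interaction (camera, Benjamini-Hochberg adjusted p = 0.0255, 0.0476 and 0.00131). The medians were 0.13, 0.14 and -0.16, and these tests used the preset correlation. With all libraries and an estimated correlation, the camera adjusted p was 0.875 for TNF in control cells and 0.653 for ALAL1 siRNA without TNF. Under SART3 siRNA without TNF, the U4/U6 list had 2 of 27 higher and 1 lower, and that 1 was SART3 itself (median 0.05). In the same contrast the medians were -0.03 for the 9 checkpoint ligands, -0.05 for the 43 G1/S genes, -0.17 for the 21 histone genes and 0.06 for the 44 oxidative phosphorylation genes. The 7 fibroblast and 5 leukocyte markers had medians of -0.01 and -0.32. Fewer than 3 endothelial markers were kept by the filter, and the mitochondrially encoded genes were listed at 0, so neither list was tested.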

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

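The tests of shared controls, depth, the p53 regulators and the library that stands apart, the scan for 7-base sequences, its comparison with other orderings that are not 1-base shifts, the lists limited to members without the sequences, and the counts of other splits were chosen after the results were seen.

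Hypoxia and glycolysis genes passed as a list for the SART3 by TNF interaction (camera, Benjamini-Hochberg adjusted p = 0.0138, median -0.20, 9 of 32 genes above 0). The adjusted p was 0.0443 with an estimated correlation, and 0 members were called. Without control siRNA + TNF replicate 3 the camera Benjamini-Hochberg adjusted p was 0.0339 at the preset correlation (median -0.181). No explanation was tested.

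Many of the genes lower under each siRNA carried 1 short sequence in the 3′ UTR. GACATCA, chosen as the strongest of 15675 sequences under ALAL1 siRNA without TNF, was in 27.7% of the genes called lower in the separate libraries with TNF and in 6.7% of the others. In those libraries the median log2 change was -0.22 with it and 0.02 without it, a difference of -0.309 after adjustment for UTR length and GC content (permutation p = 0.0001, the smallest the permutations can give). A candidate explanation is siRNAs acting on unintended transcripts through a short match, with further copies going with lower values (-0.129 after the same adjustment); the siRNA sequences were not used here, so this is a hypothesis. UTR composition or length is argued against by other orderings of the same bases, whose lowest t was -9.84, or -4.85 without 1-base shifts, against -25.50. An effect of the whole transcript stays open, since the same bases in coding regions went with -0.213, between what the predictions required.

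For SART3 siRNA the sequence was AAATGAA, chosen without TNF, which in the libraries with TNF was in 57.1% of the genes called lower and 26.8% of the others, with an effect of -0.105 (permutation p = 0.0001, the smallest the permutations can give) and -0.115 for further copies, both after the same adjustment. The unadjusted medians there were -0.006 with the sequence and 0.002 without it. In the coding region of genes without AAATGAA in the 3′ UTR, the sequence went with -0.048 with TNF (interval -0.066 to -0.031). This was weaker than -0.105 in the 3′ UTR but negative over the whole interval. A property of the whole transcript therefore stays open. Over all orderings, the comparison set beforehand could not tell: the lowest t was -13.36 against -14.40, for the 1-base shift AAAATGA, which overlaps the sequence. Among unshifted orderings, chosen afterwards, the lowest t was -4.95, which argues against UTR composition as the whole explanation. Without TNF the sequence AAAAAAA had a t of -7.94, so a part from base composition stays open. Among the genes searched, 1752 were called for ALAL1 siRNA and 901 for SART3 siRNA, both without TNF. Of these, 1430 (670 higher, 760 lower) and 477 (221 higher, 256 lower) lacked the 7-base sequence in the 3′ UTR. Genes with it in the coding region were not left out, and there it went with -0.213 and -0.048 with TNF. The candidate action on unintended transcripts is therefore not removed from these counts. Loss of the targeted transcripts stays a possible explanation for these genes, untested, because the labels name 1 siRNA condition per target.

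NF-kB target genes and chemokines were lower under SART3 siRNA. For the chemokines with TNF, the sequence AAATGAA in the 3′ UTR as the whole cause is argued against by the 21 members without it there, which were still lower (camera, Benjamini-Hochberg adjusted p over all lists 0.00114, and 0.0134 with an estimated correlation). It stays open for the chemokines without TNF (0.0134, and 0.0547 with an estimated correlation) and for the NF-kB target genes (0.0682 without and 0.0909 with TNF, and 0.144 and 0.193 with an estimated correlation), where the call ended on 25 of 40 members at medians of -0.18 (quartiles -0.26 and 0.06) and -0.12 (-0.30 and 0.01) against -0.21 (-0.37 and -0.03) and -0.15 (-0.31 and 0.01) for the whole list. For the NF-kB list, chance values of the controls are argued against by separate control sets (larger camera adjusted p = 0.000425). Without TNF the adjusted p was 0.0192 with an estimated correlation. The control siRNA + TNF library that stands apart is argued against by its omission (camera adjusted p = 0.000393). Both sets received control siRNA, so these tests cannot address an effect of that siRNA. Under ALAL1 siRNA the chemokines also had medians below 0 (-0.169 without and -0.285 with TNF). They did not pass with all libraries (camera adjusted p = 0.0732 and 0.0867). A biological effect of SART3 loss stays open.

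The p53 target genes were higher under both siRNAs. Chance values of shared controls are argued against by the separate control sets with and without TNF, since the largest camera adjusted p with an estimated correlation was 0.00705 over 4 comparisons. Depth is argued against because recovered reads were higher in the knockdown in 2 of 4 comparisons and lower in the others. Of the genes that restrain p53, the RNA of MDM2 and PPM1D showed no large fall, with a lowest 95% bound of -0.341 (MDM2, ALAL1 siRNA without TNF). PPM1D intervals lay above 0 in all 4 comparisons. Both genes are themselves raised by p53, so these levels cannot decide whether a loss of either came first. A fall of MDM4 stays open, with a lowest bound of -0.679 (SART3 siRNA without TNF). A response to transfected siRNA that differs from control siRNA is possible and was not tested.

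Other splits were counted for each comparison. For the pairwise comparisons the 10 splits of 3 against 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 453, 1979, 994, 1668, 348, 412 and 651 genes for TNF in control cells, ALAL1 siRNA, SART3 siRNA, ALAL1 siRNA with TNF, SART3 siRNA with TNF, TNF under ALAL1 siRNA and TNF under SART3 siRNA, and the highest other split gave 0 in each. Every other split mixes libraries of both groups, so the group difference enters the spread and few calls can arise. The 0 is therefore no support for the real split. For the interactions, the real count of 0 is reached by any split, so the 100 drawn decide nothing. Their highest counts, 407 for ALAL1 and 1229 for SART3, point to a structure of the samples, that of the siRNA groups: the SART3 split exchanged the siRNA labels of 0 libraries without TNF and of all 3 with TNF, so that the knockdown effects add by construction, and the ALAL1 split exchanged 3 and 1.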

How the results depend on the processing

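Fits without control siRNA + TNF replicate 3 for comparisons that do not use it, overlaps across TNF states, and lists limited to members without the 7-base sequences, were chosen after the data were seen. Counts are listed for TNF in control cells, ALAL1 siRNA, SART3 siRNA, ALAL1 siRNA with TNF, SART3 siRNA with TNF, TNF under ALAL1 siRNA and TNF under SART3 siRNA. With a log2 change of at least 1 they were 129, 331, 128, 250, 51, 137 and 159, by construction fewer. Sample weights gave 836 for TNF in control cells, 3155 for ALAL1 siRNA and 675 for TNF under ALAL1 siRNA. Fits of the compared groups alone gave 241, 2971, 882, 57 and 233 for TNF in control cells, ALAL1 siRNA, ALAL1 siRNA with TNF, SART3 siRNA with TNF and TNF under SART3 siRNA. DESeq2 gave 537 for SART3 siRNA with TNF and 141 for the SART3 interaction. The cause was not tested. Leaving out 1 library gave ranges, in the order above, of 269 to 379, 1100 to 2428, 431 to 1155, 937 to 1484, 230 to 516, 256 to 469 and 330 to 1199. The ALAL1 interaction stayed at 0 in limma (550 genes at an unadjusted p under 0.05; edgeR and DESeq2 0), and the SART3 interaction ran from 0 to 239 (1926 genes at an unadjusted p under 0.05; edgeR 0). The overlap ran from 69 to 175 without TNF and from 29 to 76 with TNF. Of 7552 alternative values of the 421 named gene results, 6877 kept direction and threshold and 675 kept only direction, 447 of them with a replicate left out; 0 reversed. Replicate numbers were not taken to pair the samples. Of 45 same-numbered pairs from different groups, 13 had r over 0.1, with a range from -0.235 to 0.32. Of 18 samples, 9 correlated best with their own number. These values were not set beside a chance rate, so a partial pairing stays open. The replicate block gave 84 genes for the SART3 interaction and moved no other total over 1.5 times (114 against 70 higher for SART3 siRNA with TNF), and all 45 list calls kept. At these depths 59% of simulated log2 changes of 1 were recovered for ALAL1 siRNA without TNF.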

Other observations

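Control siRNA + TNF replicate 3 stood apart from its group, with a chi-square per gene of 16.3 and 19.09 to its mates against 5.10 between those. In the SART3 siRNA + TNF group the values were 12.4 to 13.4. In SART3 siRNA + TNF replicates 1, 2 and 3, BCL2A1 was at 17.3, 128.0 and 23.2, and IL1A at 204.2, 908 and 416. Among the pseudogenes called for ALAL1 siRNA without TNF, 43 of 57 were higher, and with TNF 6 of 15. RP11-231D20.2, chosen after its values were seen and paired with no other name by the tables used here, was at 31.96 ± 3.60 with control siRNA, 7.24 ± 5.09 with ALAL1 siRNA and 31.4 ± 4.13 with SART3 siRNA (log2 -2.25 under ALAL1 siRNA, limma, Benjamini-Hochberg adjusted p = 0.000585). With TNF the levels were 31.4 ± 5.53, 7.36 ± 1.30 and 33.9 ± 3.81 (log2 -1.95 under ALAL1 siRNA, limma, Benjamini-Hochberg adjusted p = 0.00213).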
